A study of Mus musculus with 6 samples.

How the data were processed

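RNA of 6 libraries of mouse CD4+ T cells was extracted with TRIzol and made into transcriptome libraries with the VAHTS Universal V5 kit, per the labels' protocols. The submitters' processing notes name fastp, HISAT2, HTSeq, R 3.2.0 and DESeq2 and the mouse assembly GRCm39, without their order or settings. The annotation, the strand setting and the other versions are not given in the sources used here. The authors deposited 1 table of raw read counts per gene and 1 table of FPKM values per gene, each with a column for every library, and both were used as deposited. The table listed 21362 gene names, of which 20421, or 95.6%, matched a RefSeq symbol and 20561 matched a current or older symbol. It held 0 genes without a read in every library. The mitochondrially encoded genes appear under RefSeq names such as COX1. The deposited FPKM values were the counts divided by gene length and library total, with the ratio of count to FPKM differing between libraries by the ratio of totals within a relative 1.63e-06. FPKM therefore serves as another scaling of the same reads and not as separate evidence. The reference used here was of another assembly, so gene names were used and no coordinates are printed.

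The labels give no treatment, so no group was formed, no library was averaged with another, and no test between libraries as replicates was made. Counts were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3, with factors from 0.958 to 1.04, and expressed as CPM of the scaled total. Ranges were computed on log2 CPM with a prior count of 2, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Genes with a mean of at least 1 CPM over the 6 libraries were kept. The range of a gene is the difference between its highest and lowest library, and fold ranges are on the log2 scale with the prior count, which shrinks those of low genes. Counting error was simulated by reallocating each gene's reads among the libraries in proportion to their scaled totals, 20 times. Reads of PCR-amplified libraries without molecular identifiers are not independent molecules, so these draws and the exact Clopper-Pearson 95% intervals cover counting error only. A floor of 3 counts stood for between 0.0791 and 0.0966 CPM, depending on the library.

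Before the data were examined, 44 gene lists with 625 names were fixed for T cell states, cell programmes, sorafenib targets, RNA quality and other cell types. For each list with at least 3 measured genes, 34 in all, the level in a library was the median over members of log2 CPM minus the gene's own median over the libraries. The range of that level was set against 10000 random lists of the same size, matched on deciles of expression, and its percentile describes these libraries without a p-value. Genes shared between lists count in each. The genes named were also fixed by rule. They are 12 T cell genes whatever their values, the 10 genes with the highest mean CPM, the 20 with the largest range among genes with a mean of at least 10 CPM, and the most abundant and the most variable member of each list. For other cell types, members with a mean of at least 10 CPM were added, which gave 111 genes. Unnamed gene models and antigen receptor segments were left out of the 20. Results for 5 of the genes named by the rule are not reported here. The receptor constant genes and Y-linked genes of the lists were not analysed here. Symbols were read as the table gives them, and genes with near-identical copies, such as stefins, granzymes, ribosomal proteins and glycolysis genes with pseudogenes, may gain or lose reads in ways that could not be checked from counts.

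The procedure was tested on simulated counts drawn from the means and totals of the 6 libraries, over 11516 genes, including 200 changed ones. Genes made 3-fold or 6-fold different were found at 2-fold or more in 100% of cases, and genes made 1.5-fold different in 1.52%. Of 11316 unchanged genes, 9 were found at 2-fold or more. Of 200 random lists, 4.5% passed percentile 95, and a list of 15 genes made 1.2-fold different reached percentile 100. Random lists scored against random lists pass at about that rate by construction. Unchanged simulated genes had the same mean in every library and differed by counting error only. Genes of the real libraries differed by more, so these list results do not measure how the percentile performs there. Mitochondrially encoded genes took from 1.90% to 2.45% of counts, 113 ribosomal protein genes from 14.9% to 15.8%, and the 10 most abundant genes from 8.37% to 8.65%. Genes with at least 1 read numbered from 17325 to 17833. The alternatives were DESeq2 1.42.0 size factors, plain total counts, the deposited FPKM values with a pseudocount of 0.1, a minimum mean of 5 CPM or none, a prior count of 0.5, each library left out in turn, mitochondrially encoded genes left out, and the mean of list members. Sequence shared with annotated pseudogenes was counted over 50-base stretches of GENCODE transcripts of the older assembly GRCm38, and its relation to FPKM across genes was tested with 100000 permutations and 10000 bootstrap draws. Random lists matched also on gene length and libraries thinned to the smallest total were added after seeing the data.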

Results

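RNA sequencing measured gene expression in 6 libraries of mouse CD4+ T cells, the T lymphocytes that help and regulate other immune cells. The series concerned regulatory T cells treated with sorafenib and cells that were not treated. Sorafenib is an oral inhibitor of several protein kinases, among them the receptors for VEGF and PDGF, used against liver and kidney cancer. The labels give each library a running number and a cell type and do not say which libraries were treated. No library was therefore placed in a group, and treated cells were not compared with untreated cells. The libraries are called library 1 to library 6 by the number in their titles, and values listed in a series are in that order. Total counts over genes were 32435799, 36080476, 36071667, 36316162, 33326634 and 34421687. Levels are CPM (counts-per-million) after scaling for library composition, and the range of a gene is its highest library against its lowest. The labels do not say whether the libraries came from separate mice or cultures, and 95% intervals cover counting error only.

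All 6 libraries carried the transcripts of helper T cells. Cd4, the co-receptor that defines the lineage, ranged from 412 CPM in library 3 to 482 CPM in library 6, and Cd3e, a signalling chain of the T cell receptor complex, from 200.3 to 218 CPM. Cd8a, the co-receptor of killer T cells, stayed between 0.231 CPM (95% interval 0.0998 to 0.456) in library 2 and 0.661 CPM (0.419 to 0.992) in library 5. Of 18 T cell identity genes fixed in advance, 15 could be measured, and 0 of these ranged 2-fold or more. Cd28, the main co-stimulatory receptor and the most abundant gene of that list, ranged from 507 to 848 CPM. Xist, the RNA of the inactive X chromosome, lay between 2539 and 2828 CPM in every library. The most abundant transcripts belonged to protein synthesis, mitochondria and glycolysis. Eef1a1, a translation elongation factor, led with a median of 24650 CPM, ahead of COX1, the mitochondrially encoded oxidase subunit, with 14980 CPM, and Eef2, a second elongation factor, with 10850 CPM. Rpsa, Rplp0, Rpl4, Rpl13a, Tpt1, Pkm and Pgk1 made up the rest of the 10 most abundant genes, with medians between 3915 and 6166 CPM.

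Activated and regulatory T cell genes were present at unequal levels. Il2ra, the high-affinity chain of the interleukin 2 receptor, stood at 2301, 2201, 2178, 1556, 1613 and 1778 CPM. Ctla4, an inhibitory receptor abundant on regulatory T cells, stood at 1526, 1559, 1548, 791, 771 and 809 CPM. Foxp3, the transcription factor that defines regulatory T cells, was far lower and varied in another order, with 7.37, 7.66, 7.86, 11.9, 13.4 and 11.2 CPM. Its 95% intervals ran from 6.45 to 8.39 CPM in library 1 and from 12.2 to 14.6 CPM in library 5. Ikzf2, which encodes the factor Helios, ranged from 23.4 to 26.5 CPM, and Tnfrsf18, which encodes GITR, from 298 to 348 CPM. Il10, an anti-inflammatory cytokine gene, had the largest range of the regulatory T cell list, at 228, 218, 224, 67.2, 69.8 and 75.4 CPM. Of the 19 measured members of that list, 4 ranged 2-fold or more. As a list they did not move together beyond other genes of the same abundance, with a range of 0.18 log2 units at percentile 94.6 of random lists. That percentile was 96.6 without library 2, 96.2 without library 6, 96.1 with DESeq2 size factors, 99.7 with the mean of members and 7.77 with plain total counts.

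Across the transcriptome, 1204 of 11516 genes with a mean of at least 1 CPM ranged 2-fold or more, which is 10.5%, and 150 genes, or 1.30%, ranged 4-fold or more. Reallocating each gene's reads among the libraries at random gave a mean of 7.95 genes at 2-fold, between 2 and 13 over 20 draws, and 0 genes at 4-fold. The median gene ranged 1.29-fold. Among the 8371 genes with a mean of at least 10 CPM, 279 ranged 2-fold or more and 24 ranged 4-fold or more, against 0 at either size in any draw. Between any 2 libraries, from 29 to 623 genes differed at least 2-fold, with a median of 555 over the 15 pairs. The numbers were not spread evenly, and no pair lay between 54 genes, for libraries 1 and 3, and 543 genes, for libraries 3 and 4. Spearman's rho across genes lay between 0.982 and 0.998 for every pair, where genes are not independent replicates. The chi-square per gene was at least 3.61 in each pair, so no 2 libraries agreed within counting error. The counts depended on the filter, with 450 and 41 genes at a mean of at least 5 CPM and 6870 and 1509 genes without a filter. With the deposited FPKM values 82 genes ranged 4-fold or more.

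**Figure D1:**
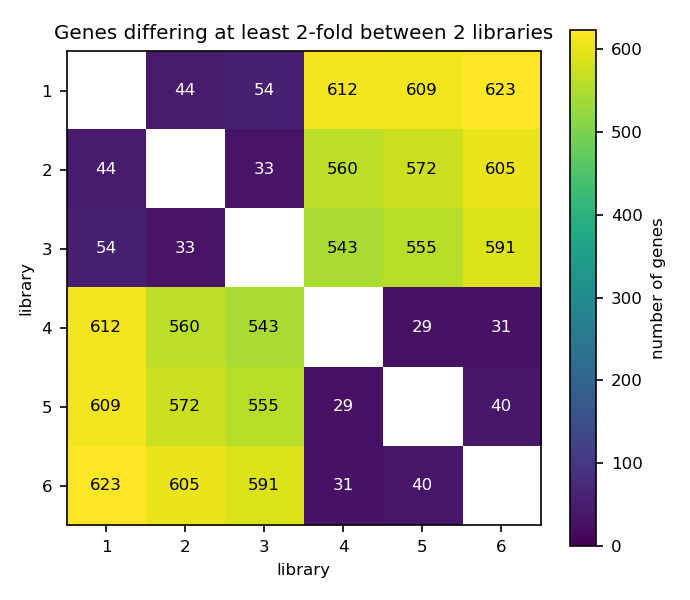
Heat map of the number of genes that differed at least 2-fold between each pair of the 6 libraries, with libraries on both axes and the number of genes as colour and as text. The smallest number was 29, between libraries 4 and 5, and the largest was 623, between libraries 1 and 6.

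Gzma, a granule protease of cytotoxic lymphocytes, had the largest range of the genes with a mean of at least 10 CPM, 31.8-fold, with 102, 73.1, 75.9, 3.66, 3.79 and 3.15 CPM. Gzmb, the granzyme that activates caspases in target cells, ranged 4.48-fold, with 913, 850, 833, 223, 204 and 242 CPM. Prf1, which encodes the pore-forming protein perforin, ranged 6.54-fold, from 2.66 CPM in library 4 to 17.7 CPM in library 1. All 7 measured genes of the cytotoxic effector list ranged 2-fold or more, and 4 of them ranged 4-fold or more. The list deviated by 0.81, 0.60, 0.57, -1.01, -0.57 and -0.81 log2 units from its genes' medians. Its range of 1.82 lay at percentile 100 of 10000 random lists. Csta2 and Cstdc4, cysteine protease inhibitors of the stefin family, ranged 8.27-fold and 9.23-fold, both lowest in library 4 and highest in library 1. Stefin genes are near-identical copies, so reads may be split among them in ways the counts do not show. The chemokine receptor gene Cxcr1 ranged 4.61-fold, from 4.20 to 19.6 CPM.

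Other genes among the 20 with the largest ranges had varied known roles. Spp1, which encodes the secreted phosphoprotein osteopontin, ranged from 6.83 to 35.6 CPM, and Ecm1, an extracellular matrix protein gene, from 144 to 682 CPM. Gipr, the receptor gene of an incretin hormone, ranged from 43.3 CPM in library 4 to 221 CPM in library 1. Tgm1, a transglutaminase gene, ranged 5.19-fold, Smtn, a smooth muscle cytoskeletal gene, 6.21-fold, and Dysf, a membrane repair gene, 5.59-fold. Akr1c18, a steroid-metabolising reductase gene, ranged 5.34-fold, Gcnt4, a glycosyltransferase gene, 4.33-fold, and Tpbg, a trophoblast glycoprotein gene, 4.69-fold. Slamf6, a lymphocyte co-receptor gene, stood at 9.69, 7.95, 8.09, 34.5, 34.9 and 31.5 CPM. Knl1 and Cenpf, which encode kinetochore proteins, and Clspn, a replication checkpoint gene, ranged 5.52-fold, 4.48-fold and 4.31-fold, each highest in library 6.

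**Figure D2:**
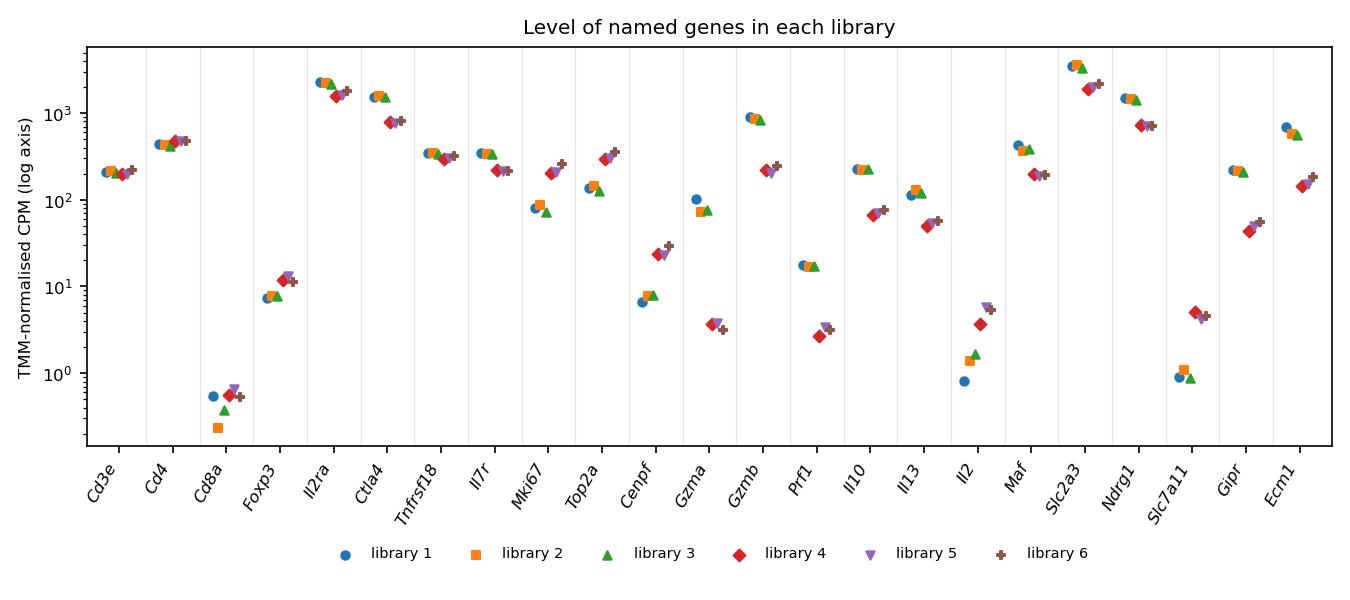
Level in CPM, on a log axis, of named genes in each of the 6 libraries, with 1 marker per library and no averages. Cd3e lies between 200.3 and 218 CPM in all libraries, while Gzma runs from 3.15 to 102 CPM.

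Genes of the cell cycle varied together. Mki67, the proliferation marker, stood at 80.1, 86.9, 72.7, 203, 209 and 260 CPM, and Top2a, the topoisomerase that untangles replicated DNA, at 138, 144, 128, 292, 302 and 358 CPM. Of 26 measured cell cycle genes, 18 ranged 2-fold or more. The list deviated by -0.45, -0.39, -0.50, 0.39, 0.45 and 0.65 log2 units in the 6 libraries, a range of 1.15 at percentile 100. Il7r, the receptor for the survival cytokine interleukin 7, stood at 343, 339, 341, 219, 214 and 214 CPM. Of the 12 measured genes of naive and memory homing, 2 ranged 2-fold or more, and the list range of 0.20 lay at percentile 88.0.

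Genes of the response to low oxygen and of glycolysis also varied as lists, by smaller amounts. Ndrg1, a stress gene induced by hypoxia, ranged 2.08-fold, with 1489, 1472, 1413, 729, 715 and 714 CPM, and Ero1a, an oxidase of protein folding, ranged from 1901 to 2793 CPM. The 17 hypoxia genes had a list range of 0.59 log2 units at percentile 100, although Ndrg1 alone ranged 2-fold or more, which it did not with plain total counts or the deposited FPKM values. Slc2a3, a glucose transporter gene, stood at 3487, 3574, 3339, 1921, 1987 and 2193 CPM, and Pkm, the pyruvate kinase gene, at 5594, 5599, 5461, 4249, 4373 and 4465 CPM. The 18 glycolysis genes had a range of 0.37 at percentile 99.97, or 0.24 with plain total counts or the deposited FPKM values, and 0 of them ranged 2-fold. Mitochondrially encoded transcripts had a range of 0.46 at percentile 100, or 0.27 without library 2, with 2 of 12 measured members at 2-fold or more. ND6, a subunit of respiratory complex I, ranged from 15.98 CPM in library 2 to 34.4 CPM in library 6, while COX1 ranged 1.09-fold. Several mitochondrial genes and Pgk1 have nuclear copies with which they share sequence, so their levels are uncertain. Of the 27 measured nuclear genes of oxidative phosphorylation, 0 ranged 2-fold, and the list range was 0.09 at percentile 71.1.

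Early activation genes and helper subset genes gave mixed results. Il2, the T cell growth factor gene, was low and stood at 0.805, 1.39, 1.66, 3.72, 5.81 and 5.31 CPM, with 95% intervals of 0.521 to 1.19 CPM in library 1 and 5.03 to 6.67 CPM in library 5. Tnfrsf9, which encodes the co-stimulatory receptor 4-1BB, stood at 1749, 1763, 1690, 824, 839 and 910 CPM. The 16 activation genes had a range of 0.30 at percentile 99.8, with 4 members at 2-fold or more. The list was lowest in library 2, at -0.14, and highest in library 6, at 0.16. Il2 was also higher in library 6 than in library 2, while Tnfrsf9 was lower. Junb, an AP-1 factor gene, ranged from 510.4 to 820.1 CPM, and Fosb from 0.575 to 1.67 CPM, in the list of immediate-early and dissociation stress genes, whose range was 0.42 at percentile 99.99. The Th17 list had a range of 1.13 at percentile 99.9 over 5 measured genes, which was 0.58 at percentile 98.6 without library 1 and 0.67 at 99.5 without library 6. Of its genes, Maf, a factor shared by several helper subsets, stood at 431, 366, 385, 198, 190.4 and 196 CPM. The Th1 list had 7 of 12 measured genes at 2-fold or more and a range of 0.21 at percentile 86.0. The Th2 list had a range of 0.27 at percentile 93.7, with Il13, a type 2 cytokine gene, at 115, 128, 119, 49.6, 53.8 and 56.7 CPM. Without library 5 the Th1 list reached percentile 99.9, as it did without library 6, and the Th2 list reached 95.2 without library 3, 96.7 without library 4 and 98.2 with the mean of members. The follicular helper list, with Icos from 178 to 307 CPM, had a range of 0.22 at percentile 67.01.

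**Figure D3:**
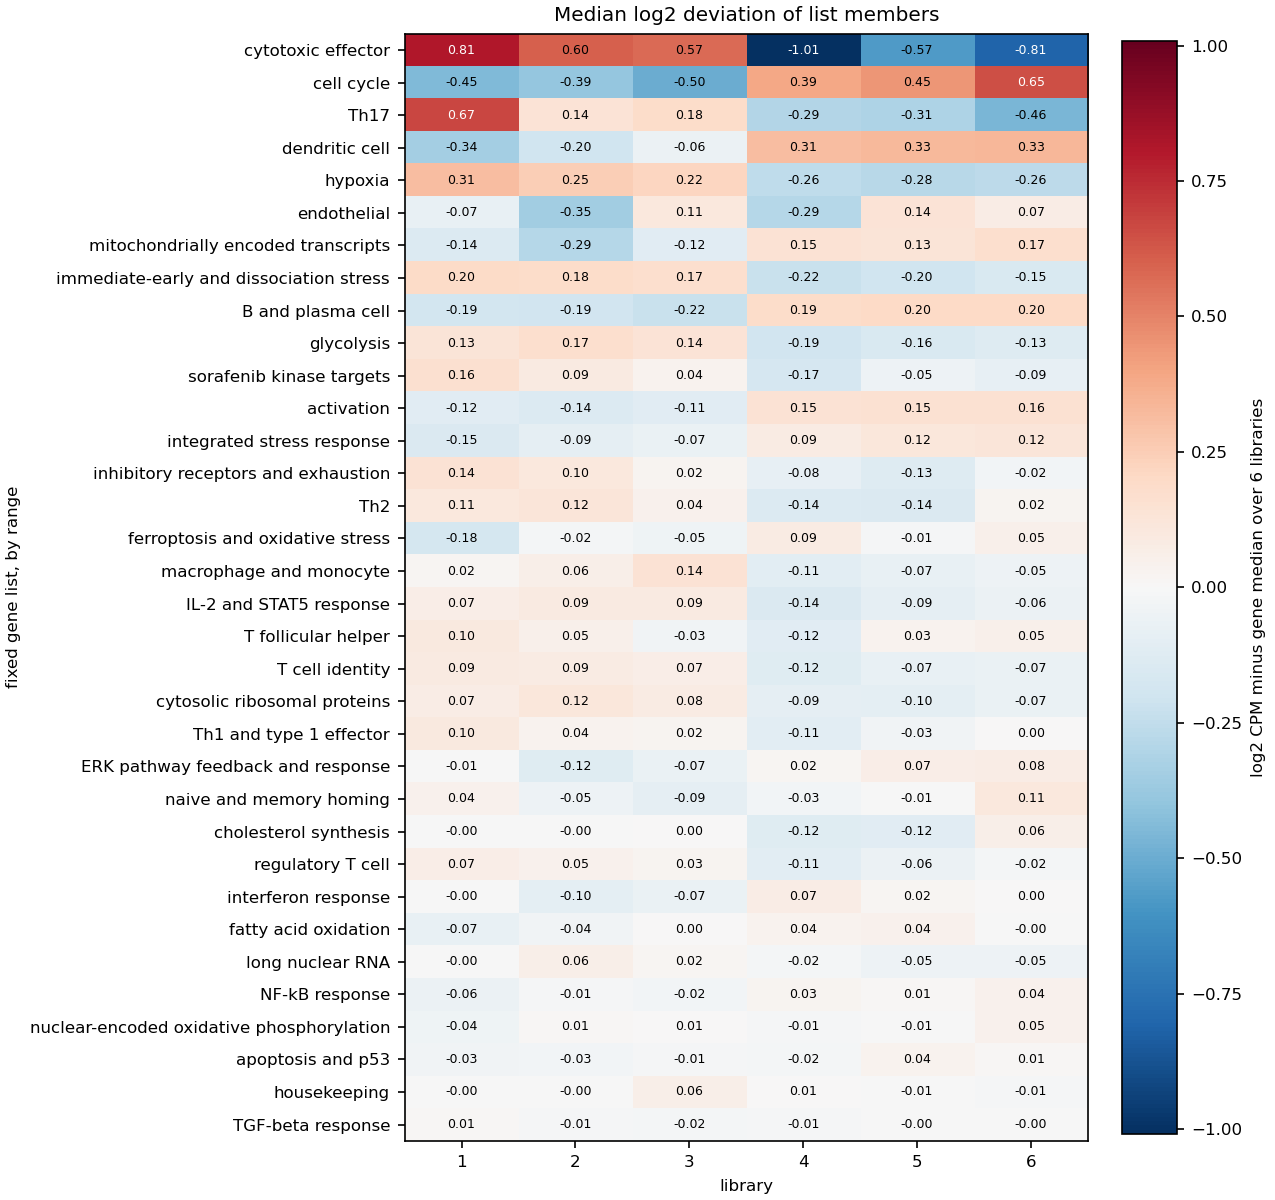
Heat map of 34 gene lists in rows, ordered by range, and 6 libraries in columns, where colour and text give the median over members of log2 CPM minus the gene's own median over the libraries. The cytotoxic effector list has the widest range, from -1.01 in library 4 to 0.81 in library 1, and the TGF-beta response list the narrowest, at 0.03.

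Kinases inhibited by sorafenib were expressed in part. Fgfr1, a fibroblast growth factor receptor gene, ranged from 1.955 to 4.70 CPM. Of 15 target genes, 8 reached a mean of 1 CPM, and 3 of these ranged 2-fold or more. The list range of 0.33 lay at percentile 97.4, but at 89.2 without library 1, 73.2 without library 4, 92.6 with the mean of members, 63.5 with plain total counts and 50.04 with the deposited FPKM values. The range itself was 0.21 without library 1, 0.15 without library 4 and 0.20 with either total counts or FPKM. Dusp4, a phosphatase gene induced by ERK signalling, stood at 350.3, 360.3, 334, 181, 191 and 199 CPM, while Dusp6, another such phosphatase gene, stood at 60.3, 56.4, 63.7, 96.3, 102 and 104 CPM. Spry2, an inhibitor of that pathway, ranged from 0.402 to 1.48 CPM. The 14 measured ERK response genes deviated by -0.01, -0.12, -0.07, 0.02, 0.07 and 0.08 log2 units, a range of 0.20 at percentile 91.6. That list passed percentile 95 without library 4, 5 or 6, at 97.6, 97.1 and 95.9, and with plain total counts, at 96.0.

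Stress response genes differed in how far they ranged. Slc7a11, the cystine transporter gene that protects cells from ferroptosis, stood at 0.901, 1.10, 0.889, 5.12, 4.17 and 4.56 CPM, with 95% intervals of 0.604 to 1.26 CPM in library 3 and 4.42 to 5.89 CPM in library 4. Ftl1, a ferritin gene, ranged from 555 to 753 CPM. The ferroptosis and oxidative stress list had a range of 0.26 at percentile 99.5, which became 0.10 at percentile 74.8 without library 1 and 0.16 at 93.8 without library 4. Ddit4, an inhibitor of mTOR signalling and the most abundant gene of the integrated stress response list, ranged from 830.0 to 1141 CPM. That list had a range of 0.27 at percentile 99.5, and 0.18 at 93.4 without library 1. It was lowest in library 1, at -0.15, and highest in library 6, at 0.12. Slc7a11, also of that list, was likewise lower in library 1 than in library 6, while Ddit4 was higher. The 18 cholesterol synthesis genes, with Srebf2 from 192 to 238 CPM and Idi1 from 12.7 to 21.0 CPM, had a range of 0.18 at percentile 96.4. Their range was 0.12 at percentile 92.6 without library 6, and the percentile was 51.8 with plain total counts and 55.7 with the deposited FPKM values. The list of inhibitory receptors and exhaustion genes, with Tox from 3.67 to 9.84 CPM and Pdcd1 from 14.6 to 20.6 CPM, had a range of 0.27 at percentile 97.48. Its percentile was 88.6, 76.6 and 88.6 without library 4, 5 and 6, 85.0 with the mean of members, 59.95 with plain total counts and 57.0 with the deposited FPKM values. Its range was 0.17, 0.13 and 0.17 without these libraries and 0.16 with total counts or FPKM. The list was highest in library 1, at 0.14, and lowest in library 5, at -0.13. Its most abundant member, Ctla4, was also higher in library 1 than in library 5, while Tox and Pdcd1 were lower.

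Of the 34 lists with at least 3 measured genes, 14 lay beyond percentile 95. Lists of randomly drawn genes would give 1.7. Members of a fixed list have related roles, and some lists share genes, so the 14 were not tested against that number. Of the 14, 8 lay beyond percentile 95 in each of the 12 alternatives run for lists. The 8 were the cytotoxic effector, cell cycle, Th17, activation, hypoxia, glycolysis, mitochondrially encoded and immediate-early lists. Signalling lists mostly lay within the random range. Ifit2, an interferon-induced gene, ranged from 2.64 to 8.88 CPM, yet the interferon list had a range of 0.17 at percentile 90.8, and 97.0 without library 3. Nfkb1 ranged from 668.5 to 972 CPM, and the NF-kB list range of 0.10 lay at percentile 40.0. Socs3, a feedback inhibitor of cytokine signalling, ranged from 218 to 335 CPM within an IL-2 and STAT5 list at percentile 92.2, and at 95.98 against random lists also matched on gene length. Tgfb1, the cytokine gene itself, ranged from 152 to 184 CPM within the TGF-beta response list, at percentile 2.42. Ccng1 and Bcl2l11, of the apoptosis and p53 list at percentile 19.3, ranged 1.36-fold and 1.70-fold. Hadha and Acadl, enzymes of fatty acid oxidation, ranged 1.17-fold and 1.47-fold within a list at percentile 65.1. Malat1, a long nuclear RNA, ranged from 777 to 1417 CPM within a list at percentile 30.4. The ribosomal protein list lay at percentile 91.3, and at 98.8, 98.3, 96.3 and 95.3 without library 1, 3, 4 and 6. The housekeeping list lay at percentile 14.8, with Gusb from 13.01 to 20.6 CPM.

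Most transcripts of other cell types were scarce. The erythroid and hepatocyte lists had 0 members at a mean of 1 CPM, with Gata1, at a median of 0.778 CPM, and Afp, at 0.810 CPM, as their most abundant members. Haemoglobin genes took at most 3.2e-05% of counts in any library. In the neutrophil list 1 gene was measured, Cxcr2, with 5.05, 5.58, 4.42, 1.16, 1.41 and 1.41 CPM, and in the mast cell list Kit, from 6.35 to 12.8 CPM. The NK and gamma delta list had 1 measured gene, Zbtb16, from 1.52 to 3.02 CPM, and the CD8 list had Cd8b1, from 8.14 to 9.57 CPM. Epcam, an epithelial adhesion gene, stood at 40.6, 44.6, 46.1, 14.0, 14.0 and 13.4 CPM. Itgb3 and Itga2b, integrin genes of platelets, ranged from 56.8 to 106 CPM and from 9.27 to 11.9 CPM, and Tagln, of the fibroblast list, from 1.03 to 2.95 CPM. Of the macrophage list, at percentile 55.8, Ctsb ranged from 218 to 278 CPM, Apoe from 18.4 to 21.8 CPM and Ccr2 from 4.27 to 11.3 CPM. The B and plasma cell list lay at percentile 73.0, with Xbp1 from 171 to 190 CPM and the B cell factor gene Ebf1 at 15.4, 14.4, 11.99, 2.08, 2.85 and 2.33 CPM. The endothelial list, with Pecam1 from 27.1 to 42.4 CPM and Eng from 5.43 to 9.22 CPM, lay at percentile 76.2.

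The dendritic cell list included antigen presentation genes at unequal levels. Cd74, the invariant chain gene, stood at 27.7, 31.8, 31.3, 78.9, 76.0 and 74.8 CPM, and H2-Eb1, a class II chain gene, at 23.0, 30.6, 31.8, 72.3, 70.7 and 68.9 CPM. H2-Aa ranged from 2.19 to 7.23 CPM. H2-Ab1, the most abundant class II gene, stood at 202, 204, 204, 136, 137 and 142 CPM, and was lowest in library 4, where Cd74 and H2-Eb1 were highest. Bst2 ranged from 43.7 to 52.0 CPM and Fscn1 from 13.1 to 15.9 CPM. Of the 9 measured genes, 5 ranged 2-fold or more, and the list range of 0.67 lay at percentile 99.97. It became 0.28 at percentile 94.9 without library 1, and 0.42 without library 2 or without library 3.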

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

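Each of 149 values per library was searched for a library far from the other 5 by Dixon's ratio, the gap to the nearest library over the whole range, against the 95% critical value for 6 samples. Of the 149 values, 2 passed. The housekeeping list stood apart in library 3, its highest, with a ratio of 0.729. Its level there was 0.06 log2 units against -0.01 to 0.01 in the others, and the list as a whole lay at percentile 14.8 of random lists. Spry2, an inhibitor of ERK signalling, stood apart in library 3, its lowest, with a ratio of 0.677. It had 0.402 CPM there, from 14 reads, against 0.983 to 1.48 CPM in the others. The rate of 1 in 20 assumes 6 values from 1 population, which the distances between the libraries argue against, so the number that passed was not set against chance. Neither value was weighed further.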

How the results depend on the processing

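The count of genes ranging 2-fold or more was 1204, and lay between 983 and 1289 under the other scalings, the other prior count and the omission of mitochondrial genes. It was 1039 to 1088 with 1 library left out. Stricter or no filtering moved it to 450 at a mean of at least 5 CPM and to 6870 without a filter. The count at 4-fold was 150, and 115 to 131 with 1 library left out. It became 41 at a mean of at least 5 CPM, 1509 without a filter and 82 with the deposited FPKM values. Without a filter counting error alone gave a mean of 3792.4 genes at 2-fold and 145.95 at 4-fold, and what made up the rest, or the lower counts at 5 CPM, was not tested. Plain total counts, to which FPKM is proportional within a gene, gave 160 genes at 4-fold, so the scaling did not account for the 82, and the added 0.1 FPKM remains. Lists past percentile 95 numbered 14, 11 to 17 with 1 library left out, and 15 with random lists also matched on gene length, an alternative chosen after seeing the data that added the IL-2 and STAT5 list. The 8 lists named as holding did so in all 12 alternatives run for lists, which leave out the filters and the omission of mitochondrial genes. Plain total counts or FPKM took the naive, oxidative phosphorylation, interferon, NF-kB and apoptosis lists past percentile 95, at 99.6, 99.7, 98.8, 95.4 and 97.6, and the mean of members the regulatory T cell, Th2 and TGF-beta lists, at 99.7, 98.2 and 96.8. Of 374 list ranges 226 moved by less than their counting error and 148 by more. For list levels per library these numbers were 1061 and 775 of 1836 and for ranges of named genes 286 and 146 of 432. Among named genes, 6 crossed 2-fold under some scaling, namely Ctla4, Tnfrsf9, Ndrg1, Kit, Fgfr1 and Dusp4. Plain total counts shifted the median gene by -0.06, -0.06, -0.05, 0.06, 0.06 and 0.05 log2 units in libraries 1 to 6. The shift was downward in libraries 1, 2 and 3 and upward in libraries 4, 5 and 6. A range between these libraries can therefore move by more than the shift in 1 library. Depth limits genes under 1 CPM, where 3 reads equal up to 0.0966 CPM.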

Other observations

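Gene families and the genes named in these paragraphs were chosen after the data were seen, as were the tests of depth by total counts, of low counts, of batch and of other cell types and the bootstrap interval below. Of 29 measured kinesin genes, whose products move along microtubules, 14 ranged 2-fold or more, as did 10 of 21 centromere protein genes and 4 of 10 genes of minichromosome maintenance, the replicative helicase. Kif15 stood at 8.72, 9.91, 9.35, 25.6, 24.4 and 32.2 CPM, and Mcm10 at 6.57, 7.28, 8.06, 18.6, 20.9 and 20.3 CPM. Kif1a, the kinesin gene with the largest range, ran otherwise, with 2.16, 2.40, 1.29, 0.738, 0.546 and 0.366 CPM. Cenpf and Mcm2 to Mcm7 also belong to the cell cycle list. Of 9 measured histone genes, 0 ranged 2-fold.

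Chemokine receptors and, with 4 of 9 measured genes at 2-fold or more, class II genes varied as well. Of 13 measured chemokine receptor genes, 8 ranged 2-fold or more and 5 ranged 4-fold or more. Ccr1 stood at 9.53, 9.37, 8.03, 1.35, 0.977 and 1.29 CPM, and Ccr3, an eosinophil and Th2 receptor gene, at 3.70, 2.83, 3.33, 0.422, 0.230 and 0.619 CPM. Of the chemokines, Ccl4 stood at 27.7, 24.1, 29.4, 12.4, 9.89 and 14.1 CPM and Ccl5 at 15.03, 15.9, 16.7, 35.8, 33.1 and 29.8 CPM. Slc7a2 and Slc7a3, transporters of cationic amino acids, stood at 3.64, 2.98, 3.07, 0.396, 0.776 and 1.97 CPM for the first and 16.9, 16.2, 16.9, 37.3, 33.8 and 34.9 CPM for the second. All 4 measured granzymes and all 3 measured stefins ranged 2-fold or more, against 3 of 17 integrins, 1 of 17 dual specificity phosphatases and 1 of 14 interferon-induced GTPase and Ifit genes. Of receptor kinases that sorafenib inhibits, Ddr1 reached 70.8 CPM, Kit 12.8 CPM and Flt3 1.74 CPM, while Kdr reached at most 0.231 CPM, Flt1 0.225 CPM, Flt4 0.193 CPM and Pdgfrb 0.501 CPM in any library.

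The 6 libraries lay in 2 sets by pairwise distance, libraries 1, 2 and 3 and libraries 4, 5 and 6, and stood at 25.7, 23.7, 21.9, -23.5, -23.5 and -24.3 on the first principal component of log2 CPM, with 77.9% of the variance. The smallest distance between the sets was 2.09 times the largest within a set, in root mean square log2 difference, and the sets were the same for the 6 distances tried. The tables argue against unequal depth, since total counts differed by 0.649% between libraries 2 and 4, of different sets, and by 10.1% between libraries 1 and 2, of the same set, a ratio of 0.0611 on the log2 scale, and against sampling noise of low counts, since the ratio of distances was 2.72 for genes with a mean of at least 10 CPM. Thinning to the smallest total, also added after the data were seen, removed few reads and decides little, with a ratio of distances of 2.08. Other library measures parted the libraries in the same way. Mitochondrially encoded genes took 2.02, 1.90, 1.98, 2.45, 2.37 and 2.41% of counts, and ribosomal protein genes 15.3, 15.8, 15.6, 14.9, 14.9 and 15.1%. Genes with at least 1 read numbered 17325, 17647, 17460, 17833, 17730 and 17799. What these differences come from was not tested. A batch of library preparation or sequencing remains open because 0 labels name one, and no biological explanation was tested, since the labels put no library in a group.

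Granzyme, perforin, stefin and Cxcr1 transcripts, abundant in killer cells and neutrophils, differed several-fold between libraries, so cells other than helper T cells were a candidate source. The values argue against CD8 T cells as the source of the difference of 709 CPM in Gzmb. Cd8a reached at most 0.661 CPM, with an upper 95% limit of 0.14% of that difference. The bound was 1%, chosen after the data were seen. Cd8b1 reached 9.57 CPM. Reads of Cd8a and Cd8b1 together were 0.978 times as high in library 1 as in library 5 (95% interval 0.831 to 1.15). Gzmb was 4.48 times as high. For NK cells, the receptor genes Ncr1, Klrb1c and Klra8 together reached at most 0.105 CPM, with an upper limit of 0.04%, under the same bound. Reads of the whole NK and gamma delta list, mostly of Zbtb16, were 2.03 times as high in library 1 as in library 5 (1.5 to 2.76). The values argue against neutrophils as the source of the difference of 46.4 CPM in Csta2. S100a8, among their most abundant transcripts, reached at most 0.0322 CPM, with an upper limit of 0.39% of it. Cxcr2, the only measured gene of the neutrophil list, was nevertheless higher in the same libraries as Csta2, with 5.05, 5.58, 4.42, 1.16, 1.41 and 1.41 CPM. Only Gzmb and Csta2 were weighed in this way, and Gzma, Prf1 and Cxcr1 were not. The ratio of these genes to the marker genes within such cells was not measured either. Gamma delta T cells stay open, because 0 of their receptor constant genes were analysed here, and no biological explanation was tested, since the labels name no group.

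Some mitochondrially encoded genes with nuclear copies were listed at low levels, and a loss of reads shared with the copies was a candidate source, although how such reads were counted is not known here and no biological explanation was tested. Across the 13 mitochondrially encoded genes, mean FPKM ran over a 2112-fold span. The 5 genes with over 95% of their 50-base stretches also in an annotated pseudogene had 11.7 to 61.6 FPKM, against 4.55 to 9617 FPKM for the other 8. Of those 8, ATP8 and ND6, with 0% of stretches shared, were low, at 4.55 and 44.0 FPKM. The rest lay between 676 FPKM for ND4 and 9617 FPKM for COX1, above all 5. Spearman's rho between shared stretches and FPKM was -0.2925 (permutation p = 0.328, two-sided, 0.328 adjusted), with a bootstrap interval of -0.81 to 0.31, so the loss of shared reads cannot be told apart from other causes with so few genes. For 18 glycolysis genes rho was 0.70 (permutation p = 0.00226, two-sided, 0.00452 adjusted), which decides nothing, because processed pseudogenes arise mainly from abundant transcripts, so that the bound set beforehand, a rho above -0.3, was wrong and is met with or without a loss. These were 2 correlations across genes, which are not independent replicates, adjusted by Benjamini-Hochberg.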
